A study of Mus musculus with 12 samples.

How the data were processed

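RNA of TM3 and TM4 cells was measured in 12 libraries, 3 in each of 4 groups. Messenger RNA was captured on poly-T beads and read as pairs of 150 bases, per the labels' protocols. The authors deposited 1 table of raw gene counts, whole numbers per gene and library, with no normalization. Per the submitters' processing notes the tools were HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR on the mm10 build. The counting options, the strand setting and the annotation release are not given in the sources used here, so antisense, overlapping and multicopy genes are uncertain. The authors' table also gives gene coordinates, a gene type and the length of each gene model in bases. Its coordinates were compared with GENCODE release M21. Of 55004 genes 54495 had their identifier there and 53585 the same start and end. The table holds 472 unannotated models, 96 of them described as retroviral, and 24780 genes without a count in any library. Some label fields name the lines as rat, while the organism field and the gene identifiers are of mouse, and the counts were used as mouse.

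Library totals ran from 15771908 to 18203115 counts, a ratio of 1.15. The limit that a count of 0 allows was set at 3 counts per library. Group means of CPM, counts relative to the library total, were computed here with library totals scaled by TMM factors. Groups were taken from the sample titles. With genes filtered by filterByExpr, 15700 were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, robust quasi-likelihood F-test) in 1 fit over all libraries with the group as the only term, 8 residual degrees of freedom and a biological coefficient of variation of 6%. The Benjamini-Hochberg adjusted p had to be under 0.05. Standard errors were computed as the absolute log2 fold change over the square root of the F statistic. Where a group has almost no counts, such a standard error can be too small for the fold change. The contrasts were MEHP against DMSO in each line, the difference of these responses (TM4 minus TM3), and TM4 against TM3 under DMSO. Genes whose libraries of the compared groups did not overlap were counted, and 3 against 3 libraries do so by chance in 10% of cases.

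The 30 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists within each contrast, and again with an estimated correlation and with fry. They covered PPAR targets, beta-oxidation, cholesterol, fatty acid synthesis, steroidogenesis, Leydig, Sertoli, junction, myoid and fibroblast, germ cell, leukocyte and endothelial markers, NRF2 targets, ferroptosis, ATF4 targets, ER chaperones, p53 targets, apoptosis, G2/M, S phase, interferon-stimulated, NF-kB, glycolysis, respiratory chain, mitochondrially encoded, xenobiotic, matrix, YAP target, immediate early and autophagy genes. The contrasts, tests, lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls in each line, 5 each way for the difference of responses and 8 each way between the lines. These genes had to pass the test, have groups that did not overlap (not asked for the difference of responses) and reach 2 CPM in the higher group, and unnamed gene models were left out. From each list it took up to 4 members that passed with the largest changes, and 16 genes were always looked up. Some genes that this rule names are not reported here.

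Settings varied one at a time were RLE and upper-quartile factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.2, a threshold of 0.01, a replicate block, each library left out in turn, thinning to the smallest total and fits on only the 6 libraries compared. A correction for gene length and GC content, with splines of 4 degrees of freedom each, was added after the data were seen. GC content was known for 98.1% of the genes tested, and the other 305 took the median. The procedure was tested on simulated data, 6 times per line, with 200 changed genes among 15428 to 15453 genes in TM3 and 15416 to 15464 in TM4. The changed genes were drawn only from those above a minimum mean count. At a simulated 1.5-fold it recovered 81.0% of the changed genes in TM3 and 78.7% in TM4, and at 1.25-fold 48.7% and 45.7%. False calls were 5.76% and 5.65% of all calls. Recovery of genes with fewer counts was not measured. The share of changed genes was smaller than that called in the data, so these rates need not hold there.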

Results

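Messenger RNA was sequenced from 2 mouse cell lines of testis origin, TM3, a Leydig cell line, and TM4, a Sertoli cell line. Leydig cells make testosterone, and Sertoli cells surround and sustain the germ cells. Cells of each line were exposed for 72 h to 100 uM MEHP, the monoester that the body makes from the plasticizer DEHP, or to 0.1% DMSO, its solvent. Each of the 4 groups held 3 libraries, and the counts summed to between 15771908 and 18203115 per library. A count of 0 in a library allowed up to 0.165 to 0.190 CPM, the count scaled to the library total,, taking 3 counts as the limit, which covers counting error only. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Coordinates are those of the mm10 build, as the authors' table gives them.

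The lines differed far more than the treatments. The first principal component of log2 CPM held 92.4% of the variance and separated TM3 from TM4. The next component, with 1.73%, placed the TM4 MEHP libraries at 20.9 to 30.6 and the TM4 DMSO libraries at -27.3 to -20.5. The component after it, with 1.16%, placed the TM3 DMSO libraries at 11.6 to 23.6 and the TM3 MEHP libraries at -21.0 to -16.6. Within a group, log2 values of library pairs correlated at 0.994 to 0.996 across genes. Every such pair differed by more than sampling noise, with chi-square values of 2.40 to 11.4 per degree of freedom. Transcripts of the mitochondrial genome took 1.69% ± 0.0322 of the counts in TM4 DMSO and 1.48% ± 0.0250 in TM4 MEHP (SD, n = 3), against 1.84% ± 0.0278 and 1.80% ± 0.0177 in TM3. The 10 most abundant genes took 6.74% ± 0.0469 and 7.38% ± 0.0258 in TM3 and 6.37% ± 0.0311 and 5.78% ± 0.0329 in TM4.

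The first comparison asked which transcripts MEHP changed in the TM3 Leydig line. Genes of fatty acid synthesis and of glycolysis rose. Of 32 measured G2/M cell cycle genes 31 rose and 0 fell (32 and 0 adjusted over the list alone). Their median log2 fold change was 0.50 (camera adjusted p = 1.97e-24, adjusted p = 0.0964 with an estimated correlation). Angptl7 (ENSMUSG00000028989, chromosome 4, 148495183 to 148500460), a secreted angiopoietin-like protein, fell from 474 ± 13.9 to 122 ± 7.64 CPM (SD, n = 3). Of 15700 genes tested 2585 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test), 1419 higher and 1166 lower with MEHP, and 65 and 41 of them changed at least 2-fold. In 35.4% of the genes the MEHP and DMSO libraries did not overlap, where chance gives 10%.

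The G2/M genes included the checkpoint kinase gene Bub1 at 0.74 ± 0.08, the proliferation marker Mki67 at 0.73 ± 0.11 and Hmmr at 0.71 ± 0.07 (log2 fold change ± SE). Among 35 genes of S phase and DNA replication, 11 rose and 0 fell (14 and 0 adjusted over the list alone). These included the ribonucleotide reductase gene Rrm2 at 0.51 ± 0.08 (camera adjusted p = 9.15e-06, adjusted p = 0.0964 with an estimated correlation).

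Fatty acid synthesis and desaturation genes rose in 12 of 17 cases and fell in 0 (14 and 0 adjusted over the list alone). Acaca, which commits acetyl-CoA to fatty acid synthesis, stood at 0.76 ± 0.08, the desaturase gene Scd1 at 0.65 ± 0.06 and Me1, which supplies NADPH, at 0.62 ± 0.06. This list kept its call when the correlation between its genes was estimated (camera adjusted p = 4.75e-10, adjusted p = 0.00763 with an estimated correlation). So did glycolysis and hypoxia-responsive genes (camera adjusted p = 4.45e-10, adjusted p = 0.0397 with an estimated correlation), of which 18 of 28 rose and 0 fell (19 and 1 adjusted over the list alone). Examples were Ero1l at 0.83 ± 0.05, Pfkp at 0.80 ± 0.07 and Bnip3 at 0.76 ± 0.08. Of 24 genes of cholesterol synthesis and uptake 10 rose and 0 fell (12 and 0 adjusted over the list alone). Among them were Dhcr7 at 0.50 ± 0.07 (camera adjusted p = 0.000147, adjusted p = 0.259 with an estimated correlation). Targets of ATF4 in the integrated stress response rose in 12 of 31 cases and fell in 0 (12 and 1 adjusted over the list alone). Members included the asparagine synthetase gene Asns at 0.77 ± 0.08 and the cystine transporter gene Slc7a11 at 0.65 ± 0.15 (camera adjusted p = 0.000246, adjusted p = 0.458 with an estimated correlation). Targets of NRF2, the regulator of antioxidant genes, rose in 10 of 26 cases and fell in 3 (12 and 3 adjusted over the list alone). These included Aox1 at 0.87 ± 0.10 and the glutathione transferase gene Gstm1 at 0.64 ± 0.06 (camera adjusted p = 0.000898, adjusted p = 0.259 with an estimated correlation).

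Of 18 NF-kB and inflammatory genes 8 fell and 1 rose (8 and 1 adjusted over the list alone). The acute-phase gene Saa3 fell by 1.74 ± 0.21 on the log2 scale, and the chemokine genes Cxcl1 and Ccl2 fell by 1.26 ± 0.17 and 1.04 ± 0.12. The list's call was lost when the correlation was estimated (camera adjusted p = 1.86e-05, adjusted p = 0.0964 with an estimated correlation). Autophagy and lysosome genes fell in 15 of 30 cases and rose in 1 (17 and 1 adjusted over the list alone). Examples were the autophagosome gene Atg12 at -0.53 ± 0.07 and the lysosomal protease gene Ctsa at -0.52 ± 0.06 (camera adjusted p = 9.84e-09, adjusted p = 0.0863 with an estimated correlation). Immediate early genes, which respond first to growth signals, fell in 8 of 24 cases and rose in 1 (11 and 1 adjusted over the list alone). Among them were Btg2 at -0.81 ± 0.08 and Nr4a1 at -0.74 ± 0.10 (camera adjusted p = 5.39e-05, adjusted p = 0.240 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 6 of 35 cases and rose in 0 (6 and 0 adjusted over the list alone). Members included the genes Ndufs3 at -0.35 ± 0.07 and Ndufa4 at -0.27 ± 0.06 (camera adjusted p = 8.70e-05, adjusted p = 0.458 with an estimated correlation).

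Targets of the PPAR receptors, which sense fatty acids and switch on their use, rose in 8 of 26 cases and fell in 3 (8 and 3 adjusted over the list alone). Pdk4, which holds back glucose oxidation, stood at 0.93 ± 0.09, the lipoprotein lipase inhibitor gene Angptl4 at 0.57 ± 0.06 and Cpt1a, which admits fatty acids to mitochondria, at 0.37 ± 0.05. The lipid droplet gene Plin2 did not pass (-0.06 ± 0.06, adjusted p = 0.538). The list's call (camera adjusted p = 0.0364, adjusted p = 0.259 with an estimated correlation) was lost without 1 library, at a camera adjusted p of 0.0541 to 0.129 without TM3 DMSO replicate 2 or 3 or TM3 MEHP replicate 1 or 3 or TM4 MEHP replicate 1. YAP and TEAD targets, which follow cell tension and density, rose in 6 of 20 cases and fell in 1 (6 and 1 adjusted over the list alone). These included Foxf2 at 0.75 ± 0.10 and Crim1 at 0.42 ± 0.06 (camera adjusted p = 0.0381, adjusted p = 0.259 with an estimated correlation). The camera value was 0.0746 to 0.0922 without TM3 DMSO replicate 3 or TM3 MEHP replicate 3. Apoptosis regulators fell in 3 of 25 cases and rose in 1 (3 and 1 adjusted over the list alone). Examples were the pro-apoptotic genes Bad at -0.33 ± 0.09 and Bmf at -0.31 ± 0.07 (camera adjusted p = 0.0381, adjusted p = 0.127 with an estimated correlation). Their camera value was 0.0622 to 0.0817 without TM3 DMSO replicate 1 or 3 or TM3 MEHP replicate 3, and Bad did not pass without TM3 DMSO replicate 1 or TM3 MEHP replicate 1 (0.0507 to 0.0724).

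The other lists passed no camera test in TM3 with all 12 libraries. Left out in turn, TM3 DMSO replicate 1 gave a call for ER chaperone genes (0.0476, higher) and p53 targets (0.0404, higher), TM4 DMSO replicate 1 for xenobiotic receptor targets (0.0324, higher), and TM3 DMSO replicate 1 or 3 or TM3 MEHP replicate 2 or TM4 MEHP replicate 2 for mitochondrially encoded genes (0.0297 to 0.0456, lower). Extracellular matrix genes fell in 11 of 33 cases and rose in 7 (11 and 10 adjusted over the list alone). Among them were Postn at -2.30, or -3.62 without TM3 MEHP replicate 3, and the membrane protease gene Mmp14 at -0.68 ± 0.05. Star, which carries cholesterol into mitochondria for steroid synthesis, stood at 6.59 ± 0.997 CPM with DMSO and 6.94 ± 0.221 with MEHP, and did not pass (log2 fold change 0.07 ± 0.16, adjusted p = 0.826). The counts that rose and fell, with those adjusted over the list alone in parentheses, were 2 and 3 (3 and 3) of 14 steroidogenesis genes, 5 and 4 (6 and 5) of 31 beta-oxidation genes, 5 and 1 (7 and 3) of 20 ER chaperone genes, 2 and 2 (2 and 2) of 31 interferon-stimulated genes, 5 and 4 (7 and 4) of 29 ferroptosis genes, 5 and 3 (6 and 3) of 24 p53 targets, 3 and 0 (4 and 0) of 10 xenobiotic receptor targets and 1 and 4 (1 and 5) of 12 mitochondrially encoded genes. Among cell type markers they were 1 and 2 (2 and 2) of 11 Leydig, 3 and 2 (4 and 4) of 19 Sertoli, 5 and 2 (6 and 3) of 20 junction, 2 and 5 (4 and 5) of 13 myoid and fibroblast, 0 and 0 (0 and 0) of 5 germ cell, 0 and 0 (0 and 0) of 3 leukocyte and 0 and 1 (0 and 1) of 5 endothelial genes. Median, mean and test differed in sign for steroidogenesis genes, ferroptosis genes and the myoid and endothelial markers, and the medians of Sertoli markers and interferon-stimulated genes were 0.00. With genes lacking counts in a group at their bound or left out, the Sertoli median was -0.07.

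By the naming rule, large rises were those of Tubb4a, Prg4, Ccno, Il2rb, Col9a3, Sh3rf2, Sbk3 and Pxdc1. They ran from 1.06 ± 0.15 for Pxdc1 to 1.50 ± 0.22 for the tubulin gene Tubb4a. Prg4, the gene of a joint lubricant, rose from 8.52 ± 1.04 to 21.1 ± 2.76 CPM, and the interleukin receptor gene Il2rb stood at 1.22 ± 0.20. The other largest falls were those of Tm4sf5, Mir351, Ccdc187, Cish, Eln, Otor and Serpind1, from -1.87 ± 0.39 for Tm4sf5 to -1.17 ± 0.21 for Serpind1, the gene of a thrombin inhibitor. The elastin gene Eln fell from 12.1 ± 1.43 to 5.05 ± 0.912 CPM, and Cish, a brake on cytokine signalling, fell from 5.04 ± 0.460 to 2.10 ± 0.744 CPM. Mir351 is a microRNA gene shorter than the fragments the protocol selected, so its value is uncertain. Ccno did not pass without TM3 DMSO replicate 1 or TM3 MEHP replicate 3 (adjusted p = 0.0686 to 0.0745), nor Sbk3 without TM3 DMSO replicate 2 or TM3 MEHP replicate 1 (0.0786 to 0.0846), nor Otor without TM3 DMSO replicate 2 or TM3 MEHP replicate 3 (0.0544 to 0.0580).

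The next comparison asked the same of the TM4 Sertoli line. Genes of fatty acid oxidation, PPAR targets and interferon-stimulated genes rose, and genes of the extracellular matrix and targets of YAP fell. Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575) rose from 2.75 ± 0.194 to 54.0 ± 3.27 CPM, a log2 fold change of 4.29 ± 0.10. Pdk4 rose from 7.96 ± 0.764 to 41.5 ± 5.21 CPM, and the matrix glycoprotein gene Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133) fell from 420 ± 32.6 to 132 ± 1.77 CPM (SD, n = 3). MEHP changed 4856 of the 15700 genes (edgeR), 2503 higher and 2353 lower, with 227 and 141 at least 2-fold. Which direction held more genes depended on the scaling, with 2190 higher and 2670 lower with RLE factors and 2674 higher and 2150 lower with upper-quartile factors. The libraries of the groups did not overlap in 38.8% of the genes, where chance gives 10%.

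**Figure D1:**
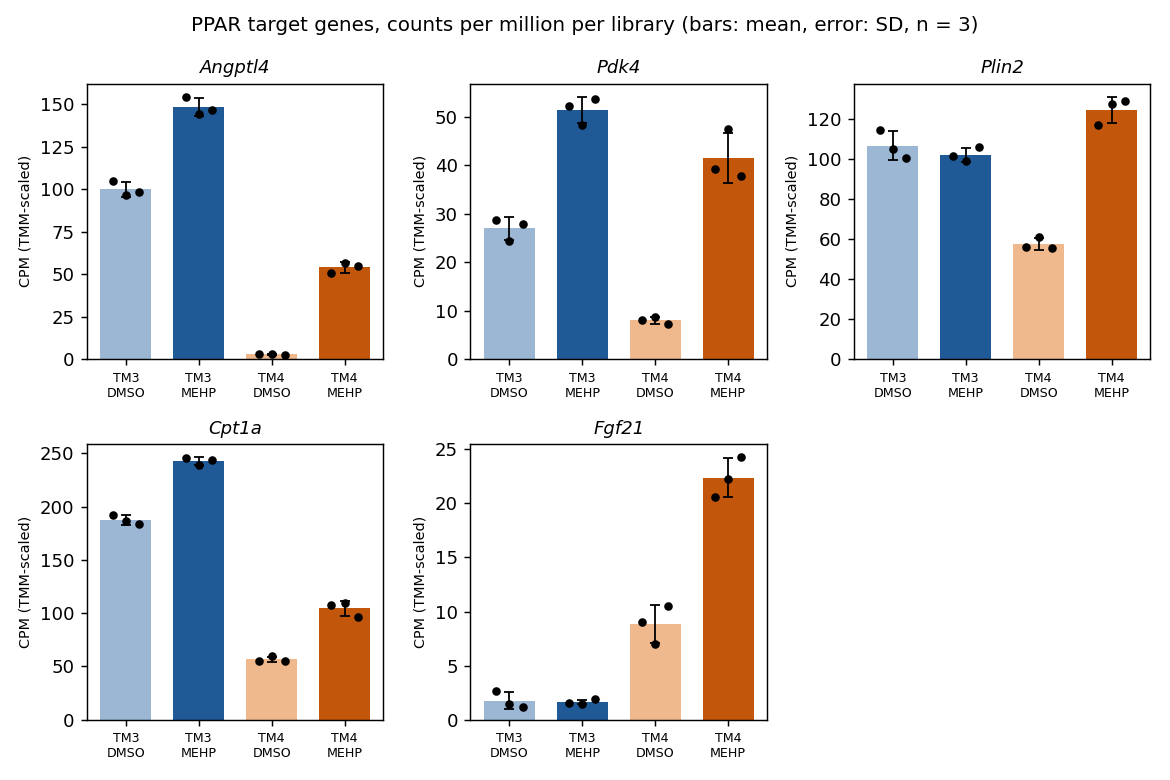
CPM, with library totals scaled by TMM factors, of 5 PPAR target genes in each library (points), with the mean (bars) and SD (error bars) of the 3 libraries of each group on linear axes from 0. Angptl4 rose from 2.75 to 54.0 CPM in TM4 and from 99.8 to 148 in TM3, Pdk4 and Cpt1a rose in both lines, and Plin2 and Fgf21 rose in TM4 and did not pass the test in TM3 (differences of 1.18 ± 0.09 and 1.46 ± 0.32 between the lines, log2 ± SE).

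PPAR target genes rose in 14 of 26 cases and fell in 2 (16 and 2 adjusted over the list alone). Members included Angptl4 at 4.29 ± 0.10, Pdk4 at 2.38 ± 0.10, the metabolic hormone gene Fgf21 at 1.35 ± 0.15 and the lipid droplet gene Plin2 at 1.11 ± 0.06. Beta-oxidation genes rose in 20 of 31 cases and fell in 1 (22 and 1 adjusted over the list alone). These included the fatty acid importers Cpt1a at 0.88 ± 0.06 and Cpt2 at 0.76 ± 0.08, the isomerase gene Ech1 at 0.88 ± 0.06 and the electron carrier gene Etfb at 1.18 ± 0.17. These lists share 12 genes, and both kept their calls with an estimated correlation (camera adjusted p = 1.44e-06, adjusted p = 0.0357 with an estimated correlation, for PPAR targets, and camera adjusted p = 7.54e-08, adjusted p = 0.0224 with an estimated correlation, for beta-oxidation). Ppard, the PPAR receptor gene that passed the filter on low counts, stood at 68.5 ± 2.78 CPM with DMSO and 66.8 ± 1.59 with MEHP in TM4, and did not pass in either line (0.04 ± 0.06 in TM3 and -0.04 ± 0.06 in TM4). Ppara stood at 0.316 ± 0.173 CPM in TM3 DMSO and 0.158 ± 0.144 in TM4 DMSO, and Pparg at 0.136 ± 0.120 in TM3 DMSO and at 0 counts in TM4, all at or near the limit of 3 counts. Interferon-stimulated genes rose in 20 of 31 cases and fell in 2 (20 and 2 adjusted over the list alone). Examples were the transcription factor gene Irf7 at 0.92 ± 0.11, as well as Ifi44 at 0.99 ± 0.09 and Usp18 at 0.98 ± 0.14. That list kept its call as well (camera adjusted p = 7.12e-05, adjusted p = 0.0191 with an estimated correlation).

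Extracellular matrix and remodelling genes fell in 25 of 33 cases and rose in 0 (26 and 0 adjusted over the list alone). Among them were Thbs1 at -1.67 ± 0.06, Postn at -1.26 ± 0.17 and Tnc at -1.09 ± 0.06 (camera adjusted p = 5.77e-17, adjusted p = 0.00600 with an estimated correlation). Postn fell in TM3 too, at -2.30, and its responses in the lines did not differ by the test with all libraries. YAP and TEAD targets fell in 12 of 20 cases and rose in 0 (13 and 0 adjusted over the list alone). Members included Crim1 at -0.98 ± 0.06, Ctgf at -0.72 ± 0.16 and Amotl2 at -0.71 ± 0.06 (camera adjusted p = 2.93e-06, adjusted p = 0.0357 with an estimated correlation). Both calls held, and the medians were -0.47 and -0.33, or -0.54 and -0.35 without the gene of each list that had no counts in a whole group and lay under the limit of 3 counts in the other. Peritubular myoid and fibroblast markers, 4 of them also in the matrix list, fell in 9 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone). These included the proteoglycan gene Dcn at -1.51 ± 0.07 and the smooth muscle actin gene Acta2 at -1.22 ± 0.06 (camera adjusted p = 1.44e-06, adjusted p = 0.0907 with an estimated correlation). Blood-testis barrier junction genes fell in 7 of 20 cases and rose in 1 (7 and 1 adjusted over the list alone). Examples were Cgn at -0.85 ± 0.11 of the tight junction and the integrin gene Itgb1 at -0.41 ± 0.05 (camera adjusted p = 0.00869, adjusted p = 0.0946 with an estimated correlation). The median (-0.10, or -0.13 without 2 genes, Espn among them, lacking counts in a group) and test of that list were negative and its mean (0.13) positive. The riser was Espn, at 0 counts in every DMSO library and 0.115 ± 0.0604 CPM with MEHP, under the limit of 3 counts. It did not pass without TM4 DMSO replicate 1, 2 or 3 or TM4 MEHP replicate 1 or 2 (adjusted p = 0.0579 to 0.0999).

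Leydig cell markers fell in 4 of 11 cases and rose in 0 (4 and 0 adjusted over the list alone), and those that fell included the growth factor gene Igf1 at -0.65 ± 0.14, the adhesion gene Vcam1 at -0.65 ± 0.06 and the receptor gene Pdgfra at -0.45 ± 0.05 (camera adjusted p = 0.0217, adjusted p = 0.0979 with an estimated correlation). Igf1 stood at -0.43 without TM4 MEHP replicate 1. The list's camera value was 0.0694 without TM4 DMSO replicate 3. ER chaperone genes and other ATF6 or XBP1 targets fell in 14 of 20 cases and rose in 1 (14 and 1 adjusted over the list alone). Among them were Sdf2l1 at -0.47 ± 0.09, Pdia4 at -0.42 ± 0.05 and Calr at -0.40 ± 0.05 (camera adjusted p = 3.63e-05, adjusted p = 0.305 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 12 cases and rose in 1 (6 and 1 adjusted over the list alone). Members included mt-Nd6 at -0.80 ± 0.06, mt-Nd5 at -0.75 ± 0.06 and mt-Cytb at -0.73 ± 0.05 (camera adjusted p = 7.12e-05, adjusted p = 0.130 with an estimated correlation). Transcripts of all 37 mitochondrial genes, a wider set than the list, took 1.48% ± 0.0250 of the counts with MEHP against 1.69% ± 0.0322 with DMSO. NF-kB and inflammatory genes fell in 8 of 18 cases and rose in 4 (8 and 4 adjusted over the list alone). These included the chemokine genes Cxcl12 at -1.25 ± 0.08 and Ccl2 at -0.85 ± 0.13 (camera adjusted p = 0.0498, adjusted p = 0.383 with an estimated correlation). The camera value of this list was 0.0506 to 0.122 without TM3 DMSO replicate 2 or 3 or TM3 MEHP replicate 3 or TM4 DMSO replicate 3 or TM4 MEHP replicate 1 or 3, and 0.0648 with RLE factors.

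ATF4 targets rose in 17 of 31 cases and fell in 0 (19 and 1 adjusted over the list alone). Examples were Slc7a11 at 0.91 ± 0.08 and, from the PPAR list too, Fgf21 (camera adjusted p = 3.63e-05, adjusted p = 0.401 with an estimated correlation). NRF2 targets rose in 14 of 26 cases and fell in 2 (14 and 2 adjusted over the list alone). Among them were the sulfiredoxin gene Srxn1 at 0.96 ± 0.08 and the heme oxygenase gene Hmox1 at 0.84 ± 0.07 (camera adjusted p = 0.000826, adjusted p = 0.305 with an estimated correlation). Ferroptosis genes rose in 12 of 29 cases and fell in 2 (14 and 2 adjusted over the list alone). Members included Lpcat3 at 1.04 ± 0.06, which places polyunsaturated fatty acids in phospholipids (camera adjusted p = 0.00145, adjusted p = 0.255 with an estimated correlation). Genes of S phase and DNA replication rose in 13 of 35 cases and fell in 4 (13 and 4 adjusted over the list alone). These included the replication factor genes Gins2 at 0.70 ± 0.10 and Rfc4 at 0.68 ± 0.12 (camera adjusted p = 0.0316, adjusted p = 0.383 with an estimated correlation). Their camera value was 0.0888 to 0.0889 without TM4 DMSO replicate 1 or TM4 MEHP replicate 3, and 0.0666 with the gene length and GC correction, which was chosen after the data were seen. The G2/M list did not pass (adjusted p = 0.0940), with 11 of 32 genes lower and 2 higher (11 and 3 adjusted over the list alone), such as the mitotic kinase gene Aurka at -0.34 ± 0.08 and the topoisomerase gene Top2a at -0.27 ± 0.06, and passed as lower without TM4 DMSO replicate 1 or 3 or TM4 MEHP replicate 2 (0.00152 to 0.0315).

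No other list passed in TM4. The counts that rose and fell, with those adjusted over the list alone in parentheses, were 5 and 10 (5 and 13) of 24 cholesterol genes, 4 and 5 (4 and 5) of 17 fatty acid synthesis genes, 4 and 6 (5 and 6) of 28 glycolysis and hypoxia genes, 2 and 1 (2 and 1) of 14 steroidogenesis genes, 6 and 8 (7 and 9) of 24 immediate early genes, 3 and 6 (3 and 6) of 30 autophagy and lysosome genes, 2 and 1 (0 and 1) of 35 respiratory chain genes, 3 and 4 (3 and 4) of 24 p53 targets, 4 and 8 (6 and 8) of 25 apoptosis regulators and 1 and 1 (1 and 1) of 10 xenobiotic receptor targets. For markers they were 1 and 4 (1 and 4) of 19 Sertoli, 0 and 0 (0 and 0) of 5 germ cell, 1 and 0 (1 and 0) of 3 leukocyte and 0 and 0 (0 and 0) of 5 endothelial genes. Single members still changed: the fatty acid synthase gene Fasn fell by 0.38 ± 0.06 and the death receptor gene Fas fell by 1.02 ± 0.17 on the log2 scale. The secreted chaperone gene Clu fell from 1.59 ± 0.682 to 0.495 ± 0.0485 CPM. Median, mean and test differed in sign for steroidogenesis genes, leukocyte markers, apoptosis regulators and respiratory chain genes.

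The other largest rises in TM4 by the naming rule were those of Trim7, Exd1, Srms, Phf11d, Slc10a3, Senp8, Extl1 and Efcab11, from 1.45 ± 0.32 for Efcab11 to 1.90 ± 0.34 for Trim7, and Phf11d rose from 2.55 ± 0.538 to 7.85 ± 1.197 CPM. The other largest falls were those of Agt, Lims2, Ctla2a, Tnr, Dnah14, Fhl1 and Crispld2. Agt, the angiotensinogen gene, fell from 2.05 ± 0.385 to 0.271 ± 0.177 CPM, and Fhl1, a LIM-domain gene of muscle, fell from 52.4 ± 2.04 to 18.8 ± 0.518 CPM. Angptl7 fell here too, from 18.9 ± 1.94 to 4.94 ± 0.157 CPM, by 1.93 ± 0.10 on the log2 scale against -1.96 ± 0.06 in TM3.

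**Figure D2:**
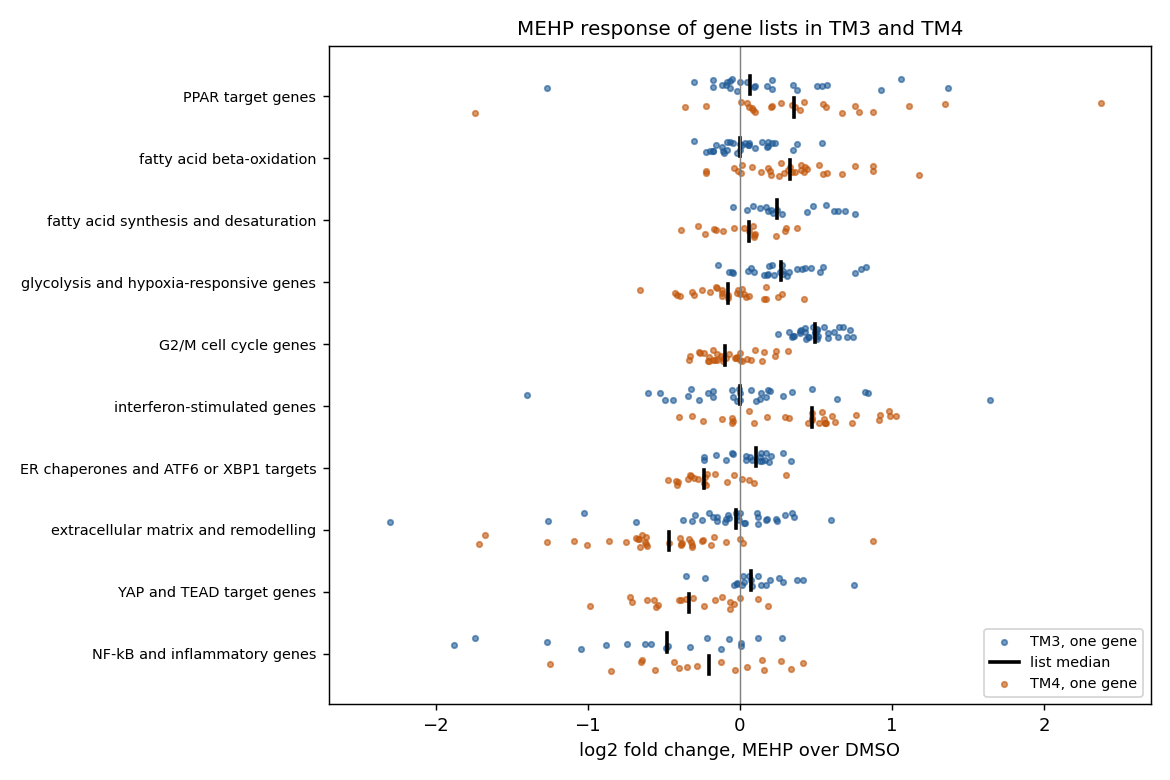
Log2 fold change, MEHP over DMSO, of each measured gene (points) of 10 gene lists in TM3 and TM4, with the median of each list (black bars); 2 points beyond 2.6 lie outside the axis. The medians of the G2/M list were 0.50 in TM3 and -0.10 in TM4, and those of the extracellular matrix list -0.02 and -0.47.

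A further test asked which genes responded differently in the lines, as the response in TM4 minus that in TM3. Relative to TM3, beta-oxidation and interferon-stimulated genes responded higher in TM4, and fatty acid synthesis, matrix and YAP target genes lower. The difference was 3.72 ± 0.12 for Angptl4, 1.45 ± 0.14 for Pdk4 (log2 ± SE), 1.46 ± 0.32 for Fgf21 and 1.18 ± 0.09 for Plin2, while Thbs1 differed by -1.68 ± 0.07 and Acta2 by -1.57 ± 0.09. Such differences compare fold changes and not amounts. Under DMSO Angptl4 stood at 99.8 CPM in TM3 and 2.75 in TM4, and with MEHP at 148 and 54.0. In all, 4134 of 15700 genes differed (edgeR, adjusted p under 0.05), 2044 higher and 2090 lower in TM4, and 236 and 234 by at least 2-fold. Angptl7 did not pass (0.02 ± 0.12, adjusted p = 0.944).

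Beta-oxidation genes had 17 of 31 higher and 0 lower in TM4 (20 and 0 adjusted over the list alone). The log2 difference was 1.33 ± 0.22 for Etfb and 0.66 ± 0.09 for Ech1. Interferon-stimulated genes had 10 of 31 higher and 3 lower (12 and 3 adjusted over the list alone). On the log2 scale the difference was 2.39 ± 0.53 for Ifi44, which lay near the limit of 3 counts in TM3, so that this value rests in part on few counts. Fatty acid synthesis genes had 11 of 17 lower and 2 higher (12 and 2 adjusted over the list alone). The difference was, in log2, -0.70 ± 0.08 for Scd2 and -0.74 ± 0.08 for Acsl3. Matrix genes had 19 of 33 lower and 2 higher (22 and 4 adjusted over the list alone), and YAP targets 11 of 20 lower and 0 higher (13 and 0 adjusted over the list alone). The log2 difference was -1.40 ± 0.08 for Crim1. These 5 lists kept their calls with an estimated correlation (adjusted p = 0.0313 with an estimated correlation for each, after camera adjusted p values of 3.23e-06, 0.00109, 8.21e-05, 2.22e-08 and 1.04e-06 in that order). G2/M genes had 30 of 32 lower and 0 higher (30 and 0 adjusted over the list alone). On the log2 scale the difference was -0.98 ± 0.12 for Aurka (camera adjusted p = 2.00e-14, adjusted p = 0.161 with an estimated correlation). Glycolysis and hypoxia genes had 15 of 28 lower and 0 higher (15 and 1 adjusted over the list alone). The difference was, in log2, -0.99 ± 0.09 for Pfkp (camera adjusted p = 3.23e-06, adjusted p = 0.0599 with an estimated correlation). PPAR targets had 12 of 26 higher and 1 lower (14 and 2 adjusted over the list alone) (camera adjusted p = 0.000291, adjusted p = 0.0893 with an estimated correlation).

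A further 9 lists differed by camera and lost the call when the correlation was estimated. Lower in TM4 on balance were 5 of them. Cholesterol genes had 13 of 24 lower and 1 higher (15 and 2 adjusted over the list alone) and adjusted p = 0.344 with an estimated correlation. ER chaperone genes had 15 of 20 lower and 1 higher (15 and 3 adjusted over the list alone) and adjusted p = 0.261 with an estimated correlation. Myoid and fibroblast markers had 6 of 13 lower and 0 higher (6 and 0 adjusted over the list alone) and adjusted p = 0.161 with an estimated correlation. Junction genes had 9 of 20 lower and 1 higher (9 and 1 adjusted over the list alone) and adjusted p = 0.0947 with an estimated correlation. Mitochondrially encoded genes had 6 of 12 lower and 1 higher (6 and 1 adjusted over the list alone) and adjusted p = 0.261 with an estimated correlation. The other 4 were higher. Ferroptosis genes had 11 of 29 higher and 2 lower (11 and 3 adjusted over the list alone) and adjusted p = 0.359 with an estimated correlation. Autophagy and lysosome genes had 10 of 30 higher and 1 lower (14 and 2 adjusted over the list alone) and adjusted p = 0.251 with an estimated correlation. Immediate early genes had 10 of 24 higher and 3 lower (10 and 4 adjusted over the list alone) and adjusted p = 0.503 with an estimated correlation. Respiratory chain genes had 4 of 35 higher and 0 lower (0 and 0 adjusted over the list alone) and adjusted p = 0.599 with an estimated correlation. Without 1 library the camera value ended the call of 3 lists. It was, for ferroptosis genes, 0.0508 to 0.0596 without TM3 DMSO replicate 1 or TM4 MEHP replicate 3, for immediate early genes 0.0542 to 0.162 without TM3 DMSO replicate 1 or 3 or TM4 DMSO replicate 1 or TM4 MEHP replicate 2 or 3, and for respiratory chain genes 0.0864 to 0.183 without TM4 DMSO replicate 1 or TM4 MEHP replicate 3. With the length and GC correction it was 0.289 for immediate early and 0.206 for respiratory chain genes, which also ended both calls. The junction list had a negative median (-0.26, or -0.33 without genes lacking counts in a group) and test and a positive mean (0.07), and median, mean and test also differed in sign for the Sertoli, NRF2 and xenobiotic lists, which did not pass.

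Of the 10 genes with the largest differences by the naming rule, Angptl4 was the only one with a mean above the limit of 3 counts in all 4 groups. The fitted differences of the other 9 depend on the prior count of the fit and are no bounds.

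Genes changed in both lines numbered 1057, of which 478 moved the same way and 579 the opposite way. With the gene length and GC correction, chosen after the data were seen, these were 612 and 624. Genes higher in TM3 and lower in TM4 numbered 365, 1.72 times the 213 of independent lists, and genes lower in both 239, 1.37 times. For genes higher in both the ratio was 1.06 and for genes lower in TM3 and higher in TM4 1.15. The count of independent lists takes every gene as equally able to pass in both lines, which genes without counts in 1 line are not. A ratio above 1 can therefore arise without a link between the responses. Across all 15700 genes, which are not independent replicates, the fold changes of the lines had a Pearson correlation of -0.025 and a Spearman correlation of -0.05. Leaving out TM3 MEHP replicate 2 lowered the genes moving the same way to 312.

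The fold changes also ran with gene length, in opposite directions in the lines, except among the shortest genes. Among the longest genes (median 9178 bases) the median log2 fold change was 0.07 (0.06 to 0.07) in TM3 and -0.06 (-0.07 to -0.05) in TM4, with 95% bootstrap intervals from resampling genes, not libraries. Among genes with a median length of 2432 bases it was -0.05 (-0.06 to -0.04) and 0.06 (0.04 to 0.07). For the shortest genes (median 1022 bases) it was -0.027 (-0.045 to -0.014) in TM3 and 0.005 (0 to 0.021) in TM4. These intervals do not measure the spread between samples.

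**Figure D3:**
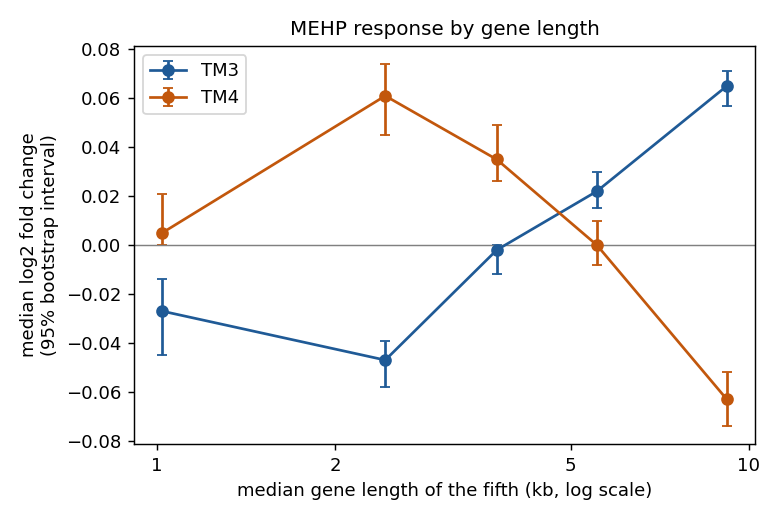
Median log2 fold change, MEHP over DMSO, in TM3 and TM4 (points, with 95% bootstrap intervals) of 5 groups of 3140 genes each by gene length, against the median length of each group in kilobases on a log axis. The intervals resample genes and not libraries, so they do not measure the spread between samples. The longest genes lay at 0.07 in TM3 and -0.06 in TM4.

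The last comparison set the lines side by side under DMSO, which also checks the line labels against cell type markers. TM4 cells held more transcripts of interferon-stimulated genes. Of 20 ER chaperone genes 20 were higher in TM4 (camera adjusted p = 7.62e-08, adjusted p = 0.343 with an estimated correlation). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), the locus of the p16 and p19 growth inhibitors, stood at 285 ± 16.2 CPM in TM4 (SD, n = 3) and at 0 counts in all TM3 libraries, at least 1580-fold higher in TM4. Etl4 (ENSMUSG00000036617, chromosome 2, 19909780 to 20810713) stood at 494 ± 25.6 CPM in TM3 and at 0 counts in the TM4 DMSO libraries, at least 2700-fold lower in TM4, both against 3 counts per library. Between the lines 12881 of 15700 genes differed (edgeR, adjusted p under 0.05), 6280 higher and 6601 lower in TM4, with 3326 and 4162 at least 2-fold. Their libraries did not overlap in 82.9% of the genes, where chance gives 10%.

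Interferon-stimulated genes were higher in TM4 in 28 of 31 cases and lower in 2 (28 and 2 adjusted over the list alone). The log2 difference was 8.85 ± 0.15 for Ifit1, and the call held (camera adjusted p = 8.37e-07, adjusted p = 0.00933 with an estimated correlation). Rsad2 had 0 counts in all TM3 libraries and 49.5 ± 4.50 CPM in TM4 DMSO, at least 274-fold higher. Of the ER chaperone genes 20 of 20 were higher (20 and 0 adjusted over the list alone). On the log2 scale the difference was 4.40 ± 0.07 for the chaperone gene Hspa5. ATF4 targets were higher in 29 of 31 cases and lower in 2 (29 and 2 adjusted over the list alone). The difference was, in log2, 8.02 ± 0.35 for Gdf15 and 7.26 ± 0.14 for Slc7a3 (camera adjusted p = 7.62e-08, adjusted p = 0.343 with an estimated correlation). Cholesterol genes were higher in 21 of 24 cases and lower in 3 (21 and 3 adjusted over the list alone). The log2 difference was 3.46 ± 0.10 for Fdps and 3.35 ± 0.06 for Msmo1 (camera adjusted p = 8.37e-07, adjusted p = 0.343 with an estimated correlation). G2/M genes were higher in 31 of 32 cases (31 and 0 adjusted over the list alone). On the log2 scale the difference was 2.17 ± 0.09 for Aurka (camera adjusted p = 2.55e-07, adjusted p = 0.343 with an estimated correlation). Matrix genes were lower in TM4 in 24 of 33 cases and higher in 6 (24 and 6 adjusted over the list alone). The difference was, in log2, -12.48 ± 0.10 for the collagen cross-linking enzyme gene Lox and -8.97 ± 0.08 for Nid2 (camera adjusted p = 0.000548, adjusted p = 0.327 with an estimated correlation). Differences between the lines this large depend on the prior count wherever the lower line is near the limit of 3 counts. Their standard errors can then be too small. Mitochondrially encoded genes were lower in 10 of 12 cases and higher in 1 (10 and 1 adjusted over the list alone). The share of the counts of all 37 mitochondrial genes differed less, at 1.84% in TM3 DMSO and 1.69% in TM4 DMSO. The log2 difference was -2.22 ± 0.06 for mt-Cytb (camera adjusted p = 0.0240, adjusted p = 0.343 with an estimated correlation).

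Markers of the named cell types were mixed. Of 19 Sertoli markers 7 were higher in TM4, the Sertoli line, and 11 lower (7 and 11 adjusted over the list alone), and of 11 Leydig markers 1 was higher and 7 lower in TM4 (1 and 7 adjusted over the list alone). Wt1, a transcription factor of Sertoli cells, stood at 167 ± 7.05 CPM in TM3 and 0.0776 ± 0.0858 in TM4, and Clu at 204 ± 11.2 and 1.59 ± 0.682. Sox9 stood at 0.361 ± 0.0197 and 2.37 ± 0.981, and Gata4 at 35.4 ± 2.39 and 52.0 ± 1.16. Nr5a1, a regulator of steroid synthesis, stood at 0.827 ± 0.390 and 0.214 ± 0.209, and passed as lower in TM4 except without TM3 DMSO replicate 3 (adjusted p = 0.0531). Its log2 difference was -1.86, or -3.02 without TM4 DMSO replicate 2, and that of Gata4 0.56, or 0.86 with the length and GC correction. The Sertoli and Leydig lists did not pass (camera adjusted p = 0.505 and 0.221), nor did Star and Amh (0.24 ± 0.16 and -0.43 ± 0.58, log2 ± SE). The receptor genes Lhcgr and Fshr, for the hormones that act on Leydig and Sertoli cells, had 0 counts in all 12 libraries, and Cyp11a1, Ppara and Pparg did not pass the filter on low counts, with Cyp11a1 at 0.164 ± 0.185 CPM in TM3 DMSO.

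The other genes named by size as higher in TM4 were Thsd7a, Ly6a, Garem1, Rxfp1, Sesn3 and Nrn1, each at 0 counts in all TM3 DMSO libraries and at least 286-fold to 816-fold higher in TM4. Vopp1 stood at 189 ± 5.98 CPM in TM4 and 0.0211 ± 0.0365 in TM3. Those lower in TM4 were Crb2, Megf6, Efemp1, Kank4, Zbtb7c, Cd38 and C1qtnf7, each at 0 counts in the TM4 DMSO libraries and at least 489-fold to 1190-fold lower. They include Crb2, a cell polarity gene, and Efemp1, which encodes a matrix protein.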

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

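Tests chosen only after the result was seen were the gene length and GC correction with its tests of matrix genes, G2/M genes and the overlap, both tests of protein-coding single-exon genes, the test of receptor genes in the form given here, and the test of retroviral models. The results below stand out because the response to MEHP differed between the lines by the interaction test (edgeR), which 4134 genes passed. Values are the response in TM4 minus that in TM3 on the log2 scale. List medians were 0.33 for PPAR targets, 0.34 for beta-oxidation, 0.43 (0.45 without genes lacking counts in a group) for interferon-stimulated, 0.26 for ferroptosis, 0.25 for immediate early, 0.17 for autophagy and lysosome and 0.13 for respiratory chain genes. They were negative at -0.40 for fatty acid synthesis, -0.24 for cholesterol, -0.56 for G2/M, -0.33 for glycolysis and hypoxia, -0.34 for ER chaperone and -0.41 for mitochondrially encoded genes. The medians were -0.59 (-0.63 without genes lacking counts in a group) for matrix genes, -0.39 (-0.41 without genes lacking counts in a group) for YAP targets, -0.86 (-0.83 without genes lacking counts in a group) for myoid and fibroblast markers and -0.26 (-0.33 without genes lacking counts in a group) for junction genes. Of these 17 lists 5 kept the call with an estimated correlation, those of beta-oxidation, fatty acid synthesis, interferon-stimulated, matrix and YAP target genes. Without 1 library the calls of ferroptosis (0.0508 to 0.0596, without TM3 DMSO 1, TM4 MEHP 3), immediate early (0.0542 to 0.162, without TM3 DMSO 1 or 3, TM4 DMSO 1, TM4 MEHP 2 or 3) and respiratory chain genes (0.0864 to 0.183, without TM4 DMSO 1, TM4 MEHP 3) were lost.

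Among PPAR targets and beta-oxidation genes the response was higher in TM4 for Angptl4 at 3.72, Pdk4 at 1.45, Fgf21 at 1.46, Plin2 at 1.18, Cpt1a at 0.50, Cpt2 at 0.66, Ech1 at 0.66 and Etfb at 1.33. With MEHP, Angptl4, Pdk4 and Cpt1a still had a lower mean CPM in TM4 than in TM3, and Plin2 a higher one. Among genes of fatty acid and cholesterol synthesis the response was lower for Acaca at -0.52, Fasn at -0.56, Scd1 at -0.62, Scd2 at -0.70, Acsl3 at -0.74, Me1 at -0.53, Dhcr7 at -0.62, Msmo1 at -0.52 and Fdps at -0.69, with Acaca at -0.33 under the length and GC correction. NRF2 targets and ferroptosis genes went both ways, with Hmox1 at 1.08, Srxn1 at 0.74 and Lpcat3 at 0.98 higher and Aox1 at -0.88 and Gstm1 at -0.36 lower. The ATF4 target Asns at -0.66 and the ER chaperone genes and related targets Hspa5 at -0.51, Sdf2l1 at -0.51, Pdia4 at -0.38 and Calr at -0.31 were lower. Also lower were the glycolysis and hypoxia genes Pfkp at -0.99, Ero1l at -0.83 and Bnip3 at -0.50 and the mitochondrially encoded mt-Nd5 at -0.65, mt-Nd6 at -0.48 and mt-Cytb at -0.31. The respiratory chain genes Ndufs3 at 0.29 and Ndufa4 at 0.23 and the autophagy and lysosome genes Ctsa at 0.63 and Atg12 at 0.45 were higher. Under the correction Ndufs3 stood at 0.19 (adjusted p = 0.114). Calls were lost, with the adjusted p in parentheses, for Ndufs3 without TM3 MEHP 2, TM4 DMSO 1, TM4 MEHP 3 (0.0513 to 0.0767) and Ndufa4 without TM3 DMSO 1 or 3, TM3 MEHP 1 or 2, TM4 DMSO 1, TM4 MEHP 2 or 3 (0.0567 to 0.112).

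G2/M genes that were lower included Bub1 at -0.64, Mki67 at -0.49, Hmmr at -0.83, Top2a at -0.88 and Aurka at -0.98, and of S-phase genes Rrm2 at -0.40 was lower and Gins2 at 0.68 and Rfc4 at 0.57 were higher. Interferon-stimulated genes that were higher included Irf7 at 0.72 and Ifi44 at 2.39, with Ifi44 at 0.496 ± 0.248 and 0.185 ± 0.106 CPM in TM3, near the limit of 3 counts. Of NF-kB and inflammatory genes Saa3 at 1.395 and Cxcl1 at 1.14 were higher and Cxcl12 at -1.53 lower. Of immediate early genes Btg2 at 0.79 was higher and Nr4a1 at -0.38 lower, the apoptosis regulator Bad at 0.77 was higher and the p53 target Fas at -1.13 lower. Calls were lost for Mki67 without TM3 DMSO 1 or 3, TM3 MEHP 1 or 2, TM4 DMSO 1 or 2, TM4 MEHP 2 (0.0531 to 0.0730), Rrm2 without TM3 MEHP 3, TM4 DMSO 3, TM4 MEHP 2 (0.0540 to 0.113), Rfc4 without TM3 DMSO 1 (0.0610), Irf7 without TM3 DMSO 1 or 3, TM3 MEHP 2 (0.0661 to 0.141) and Nr4a1 without TM3 DMSO 1, TM3 MEHP 2, TM4 DMSO 2, TM4 MEHP 3 (0.0501 to 0.0952).

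Matrix genes and myoid or fibroblast markers that were lower included Thbs1 at -1.68, Tnc at -0.72, Col3a1 at -0.91, Acta2 at -1.57 and Dcn at -1.19, and so were the YAP targets Crim1 at -1.40, Amotl2 at -0.83 and Foxf2 at -0.81 and the junction genes Itgb1 at -0.51 and Cgn at -0.53. The matrix genes Mmp14 at 0.59 and Eln at 2.13 were higher, the second with a TM4 DMSO mean of 0.147 ± 0.159 CPM, under the limit of 3 counts. Eln stood at 1.29 without TM4 MEHP replicate 2 and at 3.29 without TM4 DMSO replicate 3. The Sertoli marker Clu at -1.32 and the Leydig markers Igf1 at -0.47 and Pdgfra at -0.39 were lower. Igf1 stood at -0.25 without TM4 MEHP replicate 1 and, under the length and GC correction, at -0.28 (adjusted p = 0.363), and Pdgfra at -0.25 under that correction. Calls were lost for Eln without TM3 DMSO 1 or 3, TM3 MEHP 1 or 3, TM4 DMSO 1 or 2, TM4 MEHP 1 or 2 (0.0566 to 0.397), Clu without TM4 DMSO 2 (0.0555) and Igf1 without TM3 DMSO 1, 2 or 3, TM3 MEHP 1, 2 or 3, TM4 DMSO 1, 2 or 3, TM4 MEHP 1 (0.0558 to 0.114).

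Of the genes named by size in either line, Slc10a3 at 1.71, Senp8 at 1.51, Extl1 at 1.31, Efcab11 at 1.245 and Cish at 1.09 were higher, and Agt at -3.22, Crispld2 at -2.32, Lims2 at -1.90, Fhl1 at -1.86, Ctla2a at -1.67, Pxdc1 at -1.43, Il2rb at -0.93, Col9a3 at -0.78 and Prg4 at -1.53 lower. Prg4 stood at -0.89 without TM4 DMSO replicate 3. Agt lay near the limit of 3 counts in all groups but TM4 DMSO. It stood at 0.273 ± 0.208 CPM in TM3 DMSO, 0.349 ± 0.138 in TM3 MEHP and 0.271 ± 0.177 in TM4 MEHP, so its value rests in part on few counts. Calls were lost for Efcab11 without TM4 DMSO 3 (0.0557), Ctla2a without TM3 MEHP 1 (0.0603), Cish without TM3 DMSO 2, TM3 MEHP 1 or 2, TM4 DMSO 1 or 2, TM4 MEHP 2 (0.0538 to 0.136), Col9a3 without TM3 DMSO 2 or 3, TM3 MEHP 1 or 2, TM4 DMSO 1 or 2, TM4 MEHP 2 or 3 (0.0568 to 0.144) and Prg4 without TM4 DMSO 3, TM4 MEHP 2 or 3 (0.0523 to 0.337).

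The genes with the largest fitted differences beside Angptl4 were Aig1 at 4.95, Espn at 4.33, Syna at 2.98 and Tgtp1 at 2.82, higher, and Flrt3 at -4.16, Ush1g at -4.02, Olr1 at -3.99, Tmem255a at -3.58 and Mccc1os at -3.39, lower. These fitted values depend on the prior count and are no bounds, because each gene lay at or under the limit of 3 counts in a group. In TM4, Flrt3, Ush1g and Olr1 stood at 0.0777 ± 0.0858, 0.0988 ± 0.0882 and 0.0842 ± 0.0730 CPM with DMSO and at 0 counts with MEHP. Tmem255a and Mccc1os went from 0.179 ± 0.0904 and 0.162 ± 0.0949 to 0.0183 ± 0.0318 and 0.0198 ± 0.0343 CPM, and Espn had 0 counts with DMSO and 0.115 ± 0.0604 CPM with MEHP. Tgtp1 stood at 0.0377 ± 0.0654 and 0.366 ± 0.198 CPM in TM4. In TM3, Aig1 went from 0.219 ± 0.190 CPM to 0 counts and Syna from 0.237 ± 0.107 to 0.0419 ± 0.0363 CPM. The fitted value of Tgtp1 was 5.49 without TM4 DMSO replicate 2, that of Tmem255a -5.40 without TM4 MEHP replicate 2 and that of Mccc1os -5.22 without TM4 MEHP replicate 1. Mccc1os is an antisense gene, and with the strand setting not given its reads cannot be told from those of its partner. Calls were lost for Espn without TM4 DMSO 1, 2 or 3, TM4 MEHP 1 (0.0635 to 0.0828), Syna without TM3 DMSO 2, TM3 MEHP 2 (0.0734 to 0.0801), Tgtp1 without TM4 DMSO 1 or 3, TM4 MEHP 1 (0.0675 to 0.0828), Flrt3 without TM3 DMSO 1, 2 or 3, TM3 MEHP 1 or 3, TM4 DMSO 2 or 3, TM4 MEHP 1, 2 or 3 (0.0543 to 0.286), Ush1g without TM4 DMSO 2 or 3, TM4 MEHP 1, 2 or 3 (0.0648 to 0.141), Olr1 without TM3 DMSO 1, 2 or 3, TM3 MEHP 1 or 3, TM4 DMSO 1 or 3, TM4 MEHP 1, 2 or 3 (0.0510 to 0.131), Tmem255a without TM4 DMSO 2 (0.0737) and Mccc1os without TM4 DMSO 1, TM4 MEHP 2 or 3 (0.0658 to 0.0964).

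The libraries were also split in other ways. In TM3, 1 of 10 splits, the real one, gave as many as 2585 genes, and the highest other gave 2. In TM4 it was 1 of 10, with 4856 genes and 0 at most in the others, and between the lines 1 of 10, with 12881 and 0. These 10 splits are too few for a share under 0.05. For the difference of responses 1 of 100 splits, drawn from 200, gave as many as 4134 genes and the highest other gave 1258. These other splits mix MEHP and DMSO libraries in at least 1 line and so remove the response there. The highest of them, with 1258 genes, kept the TM4 groups and mixed those of TM3. The splits do not test whether the responses of the lines are equal. The split that keeps the TM3 groups and swaps those of TM4 was not among those drawn, so chance is not excluded.

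Matrix genes fell in TM4, G2/M genes rose in TM3 and more genes than independent lists give were higher in TM3 and lower in TM4. Fold changes ran with gene length in opposite directions in the lines, except among the shortest genes. After correction for length and GC content the median of matrix genes in TM4 was -0.449 (95% interval -0.611 to -0.315, from -0.465) and that of G2/M genes in TM3 0.465 (0.434 to 0.51, from 0.497). Both intervals resample genes and not libraries, so they do not measure the spread between samples. Relative to independent lists, genes higher in TM3 and lower in TM4 went from 1.72 to 1.73 times, genes lower in both from 1.37 to 1.62 and genes lower in TM3 and higher in TM4 from 1.15 to 1.02, while the median of genes with at least 21 exons in TM4 went from -0.058 to -0.004. These values argue against a length or GC trend as the whole cause for the matrix genes, the G2/M genes and the genes higher in TM3 and lower in TM4, but not for those lower in TM3 and higher in TM4. A difference between the cell lines, the biological explanation the design names, may account for them and stays an untested hypothesis. For the overlap, genes that could pass in only 1 line may also raise the ratio above 1, which was not tested.

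Of 267 protein-coding genes with 1 exon 57 rose and 19 fell with MEHP in TM4, with a median of 0.157, while all single-exon genes together lay at -0.062 relative to all genes (-0.037 corrected, -0.06 to -0.004), so the test on that wider set was void. After the length and GC correction the coding set lay 0.142 above all coding genes (95% interval 0.061 to 0.189, from 0.141), which argues against that trend as the whole cause. Intervals of medians in this paragraph resample genes and not libraries. DNA or unspliced RNA in the libraries was predicted to raise non-coding single-exon genes too, and their median was -0.093 (-0.126 to -0.075). Single-exon genes have no introns, so unspliced RNA need not raise them, and this test cannot decide on it. Summed olfactory, vomeronasal and taste receptor CPM rose 1.13 times with MEHP (1.047 to 1.225), or 1.23 times in a first version with 1 further gene and no TMM factors, which excludes nothing because the bound of 1.5 lay above the 1.11 times of the coding genes themselves. The receptor interval holds the 1.11 times of the coding genes, while the non-coding median was negative. These measures point different ways, so carried DNA stays open as a part or the whole of the rise. A response of such transcripts in TM4 cells stays a hypothesis that nothing here tested.

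Of 72 unannotated models described as retroviral 22 rose and 0 fell in TM3 (median 0.221), and 5 rose and 11 fell in TM4 (median -0.082). The share of the counts of all 96 models so described went from 1.83% ± 0.0367 to 2.18% ± 0.0058 in TM3 (SD, n = 3). In TM4 it was only 0.0145% ± 0.0002 with DMSO and 0.0154% ± 0.0016 with MEHP, so the TM4 calls rest on far fewer counts. Of the CPM that the 72 tested models gained in TM3, 87% lay in the 3 most abundant. Of these the first (chromosome Y, 43916465 to 43924030) went from 9238 ± 262 to 10510 ± 14.7 CPM and did not pass (edgeR adjusted p = 0.187), and the next (chromosome 14, 32115252 to 32120591) went from 4623 ± 89.6 to 5990 ± 45.5 CPM and passed (8.64e-06). The lowest MEHP share was 1.16 times the highest DMSO share, which argues against reads that merely moved between copies of the set, while an exchange with near-identical copies outside it stays open. A response of these elements in TM3 may be a biological explanation, and it was not tested.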

How the results depend on the processing

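The gene length and GC correction was chosen only after the data were seen. Under RLE and upper-quartile factors, both filters, DESeq2, limma-voom, thinning and that correction, and 6-library fits except for the difference of responses, counts of genes stayed within 1.5 times, at 2504 to 3570 in TM3, 4170 to 5090 in TM4, 3933 to 4169 for the difference of responses and 12157 to 14322 between the lines. Genes moving the same way in both lines, run only with RLE factors, both filters, DESeq2, 6 libraries and the correction, numbered 434 to 612. For the difference of responses 2044 and 2090 genes were higher and lower, and 2178 and 1991 with upper-quartile factors. Against a fold of 1.2, glmTreat gave 376, 1185 and 1481 genes, and a threshold of 0.01 gave 1492, 3220 and 2588, with 220 moving the same way, or 5 at 2-fold, as stricter thresholds must lower counts. With an estimated correlation 2, 5, 5 and 1 lists passed in place of 14, 15, 17 and 7. Between the lines fry, which compares no list with other genes, called 26 lists. Its direction was the reverse of camera's for Sertoli markers (adjusted p = 7.19e-08) and glycolysis genes (0.000395), and the cause was not tested. Between the lines Ech1 went from -0.05 to 0.16 (adjusted p = 0.0175) under the correction, and the cause was not tested. That correction also ended the calls of S-phase genes in TM4 (0.0666) and, for the difference of responses, of respiratory chain (0.206) and immediate early genes (0.289), and RLE factors that of NF-kB genes in TM4 (0.0648). Named genes were counted as kept if they stayed on their side of the threshold, with the same direction where either fit passed. They were kept in 559 of 566 cases with DESeq2, 585 of 592 with RLE factors, 570 of 592 with the correction and 375 of 387 with 6 libraries.

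With each library left out in turn, counts ran from 1742 to 2949 in TM3, 3745 to 4900 in TM4, 3458 to 4388 for the difference and 12757 to 13261 between the lines. Genes moving the same way ran from 312 to 537, lowest without TM3 MEHP replicate 2. Lists past camera numbered 11 to 16, 13 to 16, 14 to 17 and 7 to 9. Genes kept their side in 6879 of 7104 cases and lists in 1399 of 1440. Depth limits genes at or under 3 counts in both groups, whose fitted values are no bounds even where the test passed. Alternatives planned for normalized values and FPKM were not run, since the table holds counts.

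Equal replicate numbers were not taken as pairs, because no label says so and not every correlation was over 0.1. Deviations of equally numbered libraries correlated at 0.004 to 0.029 in TM3 and 0.028 to 0.12 in TM4, and the own number correlated best in 2 of 3 and 3 of 3 cases. Within TM4 the second component (18.1% of the variance) placed equal numbers close, at 18.2 with 22.5, -2.93 with 1.73 and -20.7 with -18.8, a hint of pairing from the data and not from the design, and in TM3 at 22.4 with 8.25, -25.0 with -6.51 and -3.81 with 4.61. With a replicate block 3558, 5700, 5023 and 12908 genes passed and 756 moved the same way in both lines, and the cause was not tested. Under the block PPAR targets (0.0518) and YAP targets (0.0551) in TM3 and NF-kB genes in TM4 (0.0509) did not pass, and G2/M genes in TM4 (0.0354) did, with the other lists as before.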

Other observations

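The choice of zinc finger genes, Upk1b and Upk3b followed from values already seen, and the test of mesothelial markers was set before its result. Some genes that sense or metabolize foreign compounds differed between the lines under DMSO. Cyp1b1, a xenobiotic-metabolizing enzyme gene, stood at 91.5 ± 0.994 CPM in TM3 and 0.0210 ± 0.0365 in TM4 (SD, n = 3), and the aryl hydrocarbon receptor gene Ahr at 87.8 ± 2.605 and 0.309 ± 0.225, with Cyp1b1 in TM4 and Ccl5 in TM3 under the limit of 3 counts. Of 10 xenobiotic receptor targets 7 were lower in TM4 and 2 higher (7 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.153). The chemokine gene Ccl5 stood at 0.0189 ± 0.0328 CPM in TM3 and 36.1 ± 0.918 in TM4, and Cxcl12 at 1163 ± 32.0 and 33.5 ± 1.27. NF-kB and inflammatory genes, 10 of 18 lower in TM4 and 6 higher (11 and 6 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.657).

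Under DMSO, S-phase genes were lower in TM4 in 22 of 35 cases and higher in 7 (22 and 7 adjusted over the list alone), with Rrm2 at -1.91 ± 0.09 (log2 ± SE), and that list did not pass (camera adjusted p = 0.0583). PPAR targets were lower in TM4 in 17 of 26 cases and higher in 4 (17 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0515) but passed without TM3 DMSO replicate 2 or TM4 DMSO replicate 3 (0.0392 to 0.0480). With MEHP in TM4, 98 of 348 tested genes with a zinc finger (Zfp) symbol rose and 23 fell (edgeR), beside 2503 and 2353 of all 15700 genes. No test of this group was run.

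TM3 cells under DMSO held Wt1 at 167 ± 7.05 CPM, Upk1b at 249 ± 7.86 and Upk3b at 1097 ± 22.4, against 0.0776 ± 0.0858, 0.0210 ± 0.0365 and 0.115 ± 0.148 in TM4. These genes are also active in mesothelium, the lining of body cavities, and a hypothesis is that a mesothelium-like set of genes may be active in TM3. Of 12 further markers 8 reached 2 CPM in TM3 and 4 times their level in TM4, exactly the number set beforehand as needed. They were Lrrn4, Muc16, Bnc1, Gpm6a, Krt19, Krt8, Krt7 and Nkain4, with Bnc1 at 554 ± 7.99 CPM in TM3 and 98.5 ± 5.22 in TM4 and Lrrn4 at 220 ± 15.9 and 0.160 ± 0.0577. Not among them were Msln, Calb2, Aldh1a2 and Rspo1, and Msln was lower in TM3 (190 ± 2.86) than in TM4 (365 ± 27.0). Msln and Bnc1 were thus also abundant in TM4, and other cell types use several of these keratin genes, so the hypothesis stays open.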
